A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

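Total RNA of budding yeast was sequenced by the authors from 6 libraries, 2 each of a wild type (WT), a casein kinase 2 mutant (ck2ts) and a mutant of Spt6 (spt6-7SA), grown in YPD at 30 °C to an OD600 of 0.5 and shifted to 39 °C for 2 h. Per the labels, RNA was extracted with hot phenol, depleted of ribosomal RNA and made into stranded libraries that were read from one end at 50 bp. The authors trimmed reads with Trimmomatic, aligned them with bwa to genome build R64 and counted reads per exon of Ensembl release 77 on both strands with SAMtools; tool versions were not given in the sources used here. The deposited values are raw read counts per exon and strand, with further counts for a part at the 5' and 3' end of each exon, whose extent was not given in the sources used here. The values were checked to be whole numbers with totals that differ between libraries.

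Counts of 7553 exons were summed to 7126 genes, of which 396 had more than 1 exon and 6117 took their name from the reference annotation. Of 6048 genes matched by locus tag, 6036 had the same start and end in the reference. A read that lay in several features was counted in each, so 1091 genes that overlap a gene on the other strand were left out of the antisense share and 6035 were used. Sense reads per library numbered 83375420 and 58157852 in WT, 65546990 and 56307173 in ck2ts, and 64305808 and 64198311 in spt6-7SA. Antisense reads numbered 3876104 and 2799589, 3405797 and 2885016, and 3088263 and 3202727. Over all genes together, within-group spread exceeded counting error (chi-square per degree of freedom 179 in WT, 193 in ck2ts and 111 in spt6-7SA), a figure that genes with many reads can dominate.

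Each mutant was compared with WT and the mutants with each other by the edgeR 4.0.16 quasi-likelihood test with robust dispersion (R 4.3.3), TMM scaling and Benjamini-Hochberg adjustment within each comparison, at an adjusted p of 0.05, after filterByExpr with a minimum count of 10. This left 6778 genes on the sense strand and 5496 on the antisense strand. Antisense counts were scaled by the sense library sizes and TMM factors. Antisense against sense was tested as the interaction of strand and group. The common biological coefficient of variation was 0.116 for sense and 0.163 for antisense counts. The antisense share was compared with an exact two-sided permutation test (scipy 1.17.1), which with 2 libraries against 2 cannot go below 0.33, and single libraries were given 95% Wilson intervals. Folds against a group at 0 reads were bounded with a floor of 3 reads over the group. Tables were handled with pandas 2.3.3 in Python 3.11.15 and figures drawn with matplotlib 3.10.9.

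Of 31 gene lists fixed beforehand, with 488 symbols of which 1 matched no gene, 29 were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The list of Ty elements matched no gene, and the construct and target genes were given per gene. A list of retrograde response genes was added after the data were seen.

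Named genes followed a fixed rule. For sense reads these were the 8 largest rises and 8 largest falls per mutant (5 and 5 between the mutants) among protein-coding genes that passed, had a mean of at least 10 CPM in 1 of the groups and no overlap of library values; construct and target, Ty, tRNA, snoRNA, rRNA and mitochondrially encoded genes were left out of this ranking. For antisense reads they were the 5 largest rises and 3 largest falls among all genes that passed, had at least 10 antisense CPM per sense reads in 1 group and no overlap of library values, and for antisense against sense the 3 largest fitted changes of each that passed. Construct and target genes were given first, and for each list the 2 to 4 passing members with the smallest p were named, or the only one. COX1, ATP6, COX2, Q0255, PHO12 and, in spt6-7SA, PHO11, PHO5 and SUC2 were named outside this rule, after their values were seen.

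Shared changes of both mutants were set against independent lists and against 20 simulated draws. In each draw all 6 libraries were simulated from the WT means, so both unchanged groups shared the same simulated WT group. The groups, comparisons, lists, naming rule and 91 alternatives were set before the data were examined. The alternatives covered DESeq2 1.42.0 and its size factors, count filters, scaling, overlap rules, a replicate block and leaving out each library; their effect is given in the closing section. The comparison of 3' with 5' parts (2970 genes of at least 1000 bp with a mean of at least 20 reads in each part) was added later.

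The tests were run on simulated counts with 50 genes changed at each of 1.5-fold, 2-fold, 4-fold and 8-fold. For sense reads 56%, 82%, 92% and 96% of these were called (15 false of 178 calls), for antisense reads 10%, 48%, 92% and 92% (11 of 132), for antisense against sense 2%, 24%, 88% and 92% (8 of 111), and for the 3' against the 5' part 16%, 64%, 98% and 98% (8 of 146). Of 20 simulated lists of 30 genes, the 1 list changed by 1.5-fold was called and 0 of the unchanged ones were. Genes were drawn independently, so these lists had no correlation between genes, and its effect on calls at the preset correlation was not tested.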

Results

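Strand-specific total RNA sequencing was carried out on 6 libraries of budding yeast in 3 groups of 2: a wild type (WT), a casein kinase 2 mutant (ck2ts) and a mutant of the histone chaperone Spt6 (spt6-7SA). The ck2ts strain lacked CKA1, which encodes one catalytic subunit of casein kinase 2, and carried an altered allele of CKA2, which encodes the other. The spt6-7SA strain lacked the chromosomal SPT6 gene and carried a FLAG-tagged 7S-A form of it on a centromeric URA3 plasmid. All strains were grown in rich glucose medium (YPD) at 30 °C and held at 39 °C for 2 h before RNA extraction. Reads in annotated exons on the sense strand numbered 83375420 and 58157852 in WT, 65546990 and 56307173 in ck2ts, and 64305808 and 64198311 in spt6-7SA. The design asks which transcripts change when casein kinase 2 or its target sites in Spt6 are altered, and whether reads from the strand opposite to genes rise. The spt6-7SA strain also differed from the other strains at marker loci and in lacking their inserted FLAG-histone construct. Each comparison with it covers those differences too. By its reads, ck2ts also differed from WT at LEU2 and in the 5' part of LYS2 (below), so its comparisons may cover more than the kinase genes. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples. Levels are TMM-scaled CPM, given as mean ± SD with n = 2 per group, and adjusted p-values come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named.

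The genes altered by strain construction came first. CKA1 (YIL035C, chromosome IX, 287790 to 288908, minus strand) gave 4970 and 3504 sense reads in the WT libraries and 202 and 100 in the ck2ts libraries, and 98.0% and 99.0% of the latter lay in the 3' part of the gene. CKA2 fell in ck2ts from 111 ± 4.83 to 64.0 ± 7.76 CPM (log2 fold change -0.80, SE 0.11, adjusted p = 0.000426). SPT6 stood at 366 ± 28.7 CPM in WT, fell to 250 ± 15.4 in ck2ts (adjusted p = 0.00556) and rose to 467 ± 62.2 in spt6-7SA, where it came from the plasmid (adjusted p = 0.0470). SPN1 (IWS1), which encodes a binding partner of Spt6 and was tagged in the spt6-7SA strain, fell by 0.24 on the log2 scale in ck2ts and by 0.36 in spt6-7SA. CKB1, a regulatory subunit gene of the kinase, fell by 0.50 in ck2ts (adjusted p = 0.000945), whereas CKB2 did not pass the test in either mutant (log2 fold changes -0.22 and -0.12). URA3, present in all strains through different constructs, rose in ck2ts (log2 fold change 1.13) and in spt6-7SA (0.88). BAR1, deleted in all strains, had 0 sense reads in 5 of the 6 libraries and 1 in the other. HIS3 reads in spt6-7SA, 523 and 435, lay almost wholly in the 3' part of the gene (98.9% and 96.8%), against 24.5% and 30.5% in WT. LEU2 gave 3713 and 3193 sense reads in WT and 3161 and 3338 in spt6-7SA but 1 and 4 in ck2ts, although the labels list the same leu2 deletion for every strain. LYS2, for which the labels list the same insertion allele in every strain, did not pass the test for its level in either mutant (log2 fold changes 0.14 and 0.09). The 5' part held 43.4% and 36.1% of LYS2 reads in WT, 39.5% and 33.2% in spt6-7SA, and 12.6% and 9.90% in ck2ts. Of the 10 construct and target genes measured, 1 rose, 7 fell and 2 did not pass in ck2ts (8 passed when adjusted over the list alone), and 2 rose, 2 fell and 6 did not pass in spt6-7SA (3 passed when adjusted over the list alone).

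In ck2ts against WT, genes of the general stress response rose and genes for making ribosomes fell, and nearly all transcripts of the mitochondrial genome were lost. Among nuclear protein-coding genes other than the construct and target genes, with at least 10 CPM in a group, the largest rise was at DDR2 (YOL052C-A, chromosome XV, 231570 to 231755), a multistress response gene, from 6.88 ± 0.0970 to 167 ± 84.1 CPM (24.3-fold, log2 fold change 4.60, SE 0.49, adjusted p = 0.000743). CTT1 (YGR088W, chromosome VII, 654634 to 656322), which encodes cytosolic catalase, rose 21.4-fold, from 10.6 ± 2.10 to 226 ± 24.2 CPM (adjusted p = 6.10e-06). With 1 library left out, the log2 fold change ran from 3.96 to 5.03 at DDR2 and from 4.22 to 4.63 at CTT1. Their order is therefore not fixed. HSP30, a plasma membrane heat shock protein gene, rose 18.6-fold, PUL3 17.1-fold, and the glycogen branching enzyme gene GLC3 16.3-fold. SDH9, which encodes a minor succinate dehydrogenase isoform, the proline oxidase gene PUT1 and the sulfate permease gene SUL1 completed the 8 largest rises, at 15.1-fold, 15.0-fold and 14.6-fold. Among the same genes, the largest fall was in YGR035C (chromosome VII, 557072 to 557422), from 21.2 ± 6.43 to 1.52 ± 0.824 CPM (log2 fold change -3.78, SE 0.40, adjusted p = 0.000235). With 1 library left out its log2 fold change ran from -4.50 to -3.34, against -3.95 to -3.44 at SPL2 and -3.67 to -3.48 at PHM6. Its rank is therefore not fixed. Phosphate genes followed, with SPL2 and PHM6 falling by 3.66 and 3.58 on the log2 scale and the phosphate transporter gene PHO89 by 2.68. IZH4 fell by 3.19, the glucose transporter gene HXT2 by 2.82, from 756 ± 34.6 to 107 ± 9.97 CPM, the GTPase gene RAS1 by 2.76, and the cell wall mannoprotein gene CWP1 by 2.65. Of 6778 genes tested, 4389 changed, 2203 up and 2186 down, of which 926 and 785 changed at least 2-fold.

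**Figure D1:**
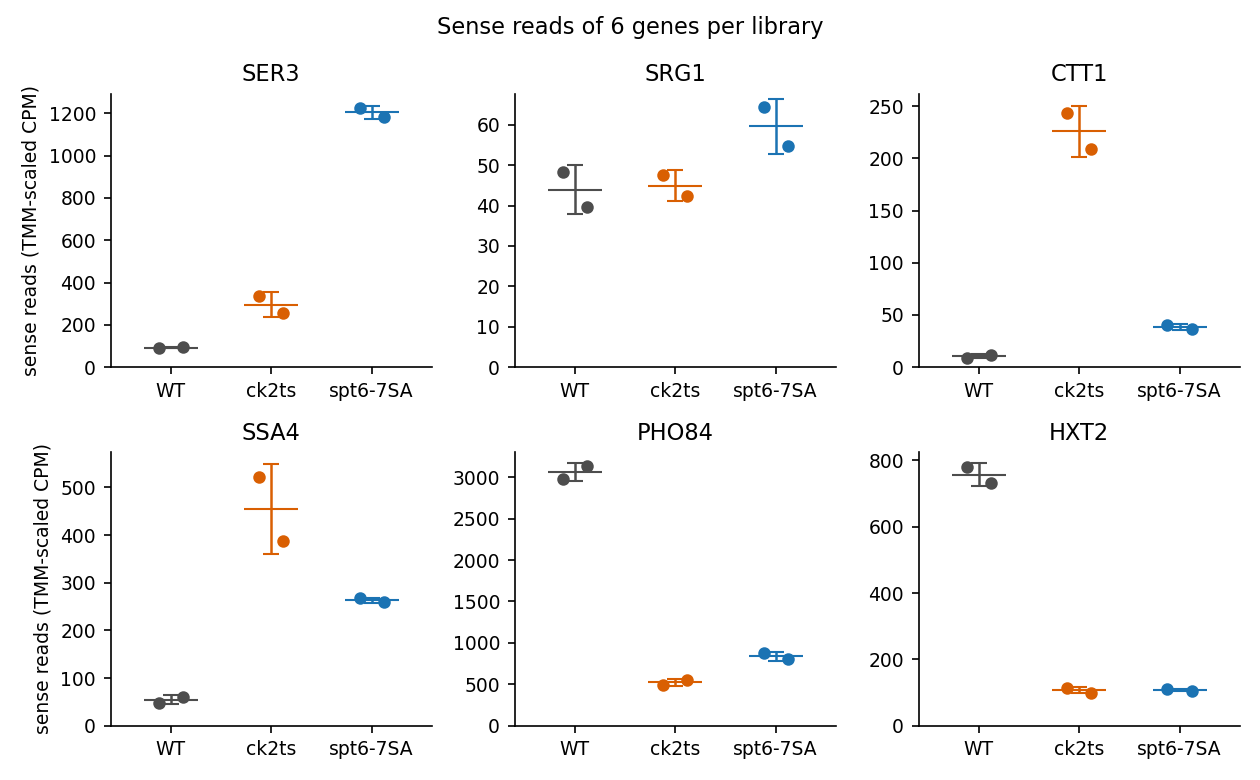
Sense reads per library of 6 genes in TMM-scaled CPM (vertical axes, starting at 0), by group; points are libraries, and horizontal lines and error bars are the mean and SD of 2 libraries. SER3 stood at 1205 CPM in spt6-7SA against 91.9 in WT, CTT1 at 226 CPM in ck2ts against 10.6 in WT, and HXT2 at 107 CPM in both mutants against 756 in WT.

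All 35 general stress (Msn2/4) genes rose in ck2ts (35 also when adjusted over the list alone), with a median log2 fold change of 2.40. Beside CTT1 and GLC3, the cell wall protein gene SPI1 rose 6.69-fold and GAD1, glutamate decarboxylase, 4.71-fold. The list stood above other genes by camera (adjusted p = 5.99e-25; adjusted p = 0.385 with an estimated correlation). Of 27 Hsf1 chaperone genes, 20 rose, 1 fell and 6 did not pass (21 passed when adjusted over the list alone). The Hsp70 gene SSA4 went from 54.1 ± 9.49 to 454 ± 94.6 CPM, the mitochondrial chaperone gene MDJ1 rose 2.82-fold and the small heat shock protein gene HSP42 6.81-fold (camera adjusted p = 1.51e-06; adjusted p = 0.385 with an estimated correlation). All 50 ribosome biogenesis genes fell (50 when adjusted over the list alone), with a median log2 fold change of -1.50; the RNA polymerase I subunit gene RPA34 went from 80.9 ± 3.64 to 28.6 ± 0.323 CPM, the nucleolar protein gene NSR1 fell by 2.23, and the helicase genes DBP3 and HAS1 by 1.80 and 1.65 (camera adjusted p = 1.15e-28; adjusted p = 0.385 with an estimated correlation). Of 138 cytoplasmic ribosomal protein genes 132 fell, 0 rose and 6 did not pass (132 when adjusted over the list alone), with a median of -1.05 (camera adjusted p = 1.70e-19; adjusted p = 0.385 with an estimated correlation). RPS7B fell by 1.80, RPL27B by 1.58, RPS26B by 1.53 and RPS16B by 1.42, with the limit that duplicated ribosomal protein genes can share reads. RNA polymerase III genes gave 12 falls and 4 rises of 21 (16 passed when adjusted over the list alone), with RPC34 falling by 1.96, RPC31 by 1.73 and RPC40 by 1.55 (camera adjusted p = 0.00353; adjusted p = 0.385 with an estimated correlation). Of 81 snoRNA genes 38 fell, 1 rose and 42 did not pass (37 passed when adjusted over the list alone), SNR71 falling by 1.90, SNR24 by 1.23, SNR59 by 1.22 and SNR191 by 0.92 (camera adjusted p = 0.00138; adjusted p = 0.385 with an estimated correlation).

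The phosphate regulon fell in ck2ts, with 13 of 16 genes down, 2 up and 1 not passing (15 passed when adjusted over the list alone; camera adjusted p = 1.94e-06; adjusted p = 0.385 with an estimated correlation). The high-affinity phosphate transporter gene PHO84 went from 3062 ± 109 to 525 ± 43.0 CPM, and VTC3, for polyphosphate synthesis, fell by 1.94 on the log2 scale. The acid phosphatase gene PHO11 fell by 1.92, and its near-identical copy PHO12, which can share its reads, by 1.93. Of 34 nuclear-encoded respiratory chain genes 26 rose, 1 fell and 7 did not pass (27 when adjusted over the list alone; camera adjusted p = 5.31e-07; adjusted p = 0.385 with an estimated correlation). CYT1, cytochrome c1, rose 9.03-fold, SDH2 8.66-fold, NDI1 3.24-fold and COR1 2.36-fold, in the same libraries that had lost most mitochondrially encoded transcripts. DNA damage response genes gave 17 rises and 0 falls of 19 (17 when adjusted over the list alone), with the ribonucleotide reductase gene RNR3 up 6.02-fold, the photolyase gene PHR1 3.29-fold and the checkpoint kinase gene DUN1 2.47-fold (camera adjusted p = 0.000244; adjusted p = 0.385 with an estimated correlation). G1/S genes gave 14 rises and 0 falls of 20 (14 when adjusted over the list alone), among them the cyclin genes CLN1 (log2 fold change 1.85), CLN2, 2.60-fold, and PCL1, 2.15-fold (camera adjusted p = 0.00171; adjusted p = 0.490 with an estimated correlation). YOX1 rose 2.69-fold. Meiosis and sporulation genes gave 15 rises and 3 falls of 24 (18 passed when adjusted over the list alone), with SGA1 up 11.4-fold, MEK1 8.28-fold and HOP1 5.70-fold (camera adjusted p = 0.00432; adjusted p = 0.483 with an estimated correlation). M/G1 daughter-cell genes gave 9 falls and 3 rises of 14 (12 passed when adjusted over the list alone), with DSE2 falling by 2.14, AMN1 by 1.21 and DSE3 by 1.15 while the replication licensing gene CDC6 rose 2.49-fold (camera adjusted p = 0.0203; adjusted p = 0.433 with an estimated correlation). Iron regulon genes gave 12 falls and 4 rises of 20 (16 passed when adjusted over the list alone), with the iron permease gene FTR1 falling by 2.15 and ARN1 by 1.33 (camera adjusted p = 0.0236; adjusted p = 0.483 with an estimated correlation). Core histone genes gave 7 falls of 8, and 8 when adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.433 with an estimated correlation). HTA2 fell by 1.77, HTB2 by 1.33 and HTA1 by 1.04, and HHF1 by 0.68, with the limit that copies of the same histone can share reads. Galactose genes gave 5 rises and 0 falls of 8 (5 when adjusted over the list alone), GAL2 rising 5.63-fold and GCY1 3.59-fold (camera adjusted p = 0.0434; adjusted p = 0.385 with an estimated correlation). That call ended without WT replicate 1 (adjusted p = 0.0511). With the mitochondrially encoded list, 16 of 29 lists passed camera in ck2ts at the preset correlation; with an estimated correlation 0 passed, 2 at an unadjusted p under 0.05, and 23 passed fry.

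The remaining lists did not pass camera in ck2ts. Histone chaperone and elongation factor genes gave 8 rises and 16 falls of 36 (24 passed when adjusted over the list alone; camera adjusted p = 0.607), with SPT21, an activator of histone genes, rising 1.92-fold. The histone methyltransferase gene SET2 fell by 0.77, the Paf1 complex gene CTR9 by 0.68 and SPT4 by 0.80. Genes used as readouts of intragenic initiation gave 8 rises and 2 falls of 14 (10 passed when adjusted over the list alone; camera adjusted p = 0.0839), with APM2 up 2.86-fold and STE11 2.13-fold. Spt6-sensitive repressed promoters gave 4 rises and 2 falls of 7 (6 passed when adjusted over the list alone; camera adjusted p = 0.341), where SER3 rose 3.22-fold and CYC1 3.69-fold, and PHO5 fell by 1.06 and SUC2 by 0.55. Alpha-cell genes gave 4 rises of 8 (4 when adjusted over the list alone; camera adjusted p = 0.0654), among them MF(ALPHA)2 at 3.19 ± 0.679 CPM against 0.311 ± 0.0010 in WT. SAG1 rose 2.77-fold. The alpha-cell list passed without WT replicate 1 (adjusted p = 0.0452) and without ck2ts replicate 2 (0.0395). A-cell genes gave 5 falls and 1 rise of 6 (6 passed when adjusted over the list alone; camera adjusted p = 0.553), the pheromone receptor gene STE2 falling by 0.83 and ASG7 rising 1.84-fold. Pheromone response genes gave 5 rises and 7 falls of 17 (12 passed when adjusted over the list alone; camera adjusted p = 0.606), with a median of -0.12, a mean of 0.09 and a downward test direction; FUS3 fell by 1.51 and STE12 by 1.41. Glycolysis genes gave 7 rises of 16 (6 when adjusted over the list alone; adjusted p = 0.215), TDH1 rising 4.05-fold and ENO1 2.54-fold. Amino acid synthesis (Gcn4) genes gave 10 rises and 18 falls of 38 (28 when adjusted over the list alone; 0.344), LEU1 rising 3.38-fold and HIS1 falling by 1.67 and ADE4 by 1.42. Cell wall integrity genes gave 12 rises and 3 falls of 21 (15 when adjusted over the list alone; 0.155), with YPS3 up 4.29-fold and CWP1 among the falls. Proteasome genes gave 13 rises and 1 fall of 34 (11 when adjusted over the list alone; 0.228), RPN9 rising 1.44-fold and PRE6 1.34-fold. Ergosterol genes gave 4 rises and 8 falls of 20 (12 when adjusted over the list alone; 0.798), with ERG9 up 1.98-fold and ERG6 falling by 0.75. G2/M genes gave 1 rise and 1 fall of 17 (1 when adjusted over the list alone; 0.878), MOB1 rising 1.34-fold and CLB3 falling by 0.50. Of 144 measured tRNA genes 12 rose and 20 fell (16 passed when adjusted over the list alone, camera adjusted p = 0.696), tD(GUC)N rising 4.62-fold. Copies of the same tRNA gene can share reads. The list also includes mitochondrial tRNA genes, so its falls do not stand for nuclear tRNA genes alone. The mitochondrial tRNA genes tH(GUG)Q and tV(UAC)Q had 111 and 151 sense reads in WT and 0 in ck2ts, at least 31.9-fold and 43.3-fold lower against a floor of 3 reads over the group.

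Mitochondrially encoded transcripts were nearly absent from both ck2ts libraries except at one stretch. Of 20 genes in the list, 18 fell, 1 rose and 1 did not pass (20 passed when adjusted over the list alone; camera adjusted p = 3.31e-55; adjusted p = 0.140 with an estimated correlation). COX1 (Q0045), a cytochrome c oxidase subunit gene, went from 424 ± 49.6 CPM in WT to 0.430 ± 0.0170, and its introns' reading frame AI1 from 385 ± 6.83 to 0.282 ± 0.0700. AI2 went from 283 ± 22.7 to 0.353 ± 0.0040 CPM and AI5_BETA from 43.8 ± 0.785 to 0.0340 ± 0.0040. COX1, AI1 and AI2 share their start with AI3, AI4 and AI5_ALPHA, and COB shares its start with BI2, BI3 and BI4. Such genes can share reads, so their falls are not separate results. The count of 18 falls and the camera tests take them as separate members. The median log2 fold change was -10.16, or -9.67 with the 5 genes at 0 reads in ck2ts set to the bound that 3 reads give. ATP6, for one, had 1086 reads in WT and 0 in ck2ts, at least 312-fold lower. The exceptions were the neighbours COX2 (Q0250, mitochondrial genome, 73758 to 74513) and Q0255 (74495 to 75984). COX2 had 19127 and 145998 reads in the ck2ts libraries against 13398 and 9470 in WT, so that replicate 2 stood 9.09-fold above replicate 1 in CPM; its adjusted p was 0.0680, and that of Q0255, which rose, was 0.0489. In spt6-7SA the genes lost in ck2ts stood together at 117% of the WT level, and 1 of the 20 list genes, AI2, rose (0 when adjusted over the list alone; camera adjusted p = 0.830).

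**Figure D2:**
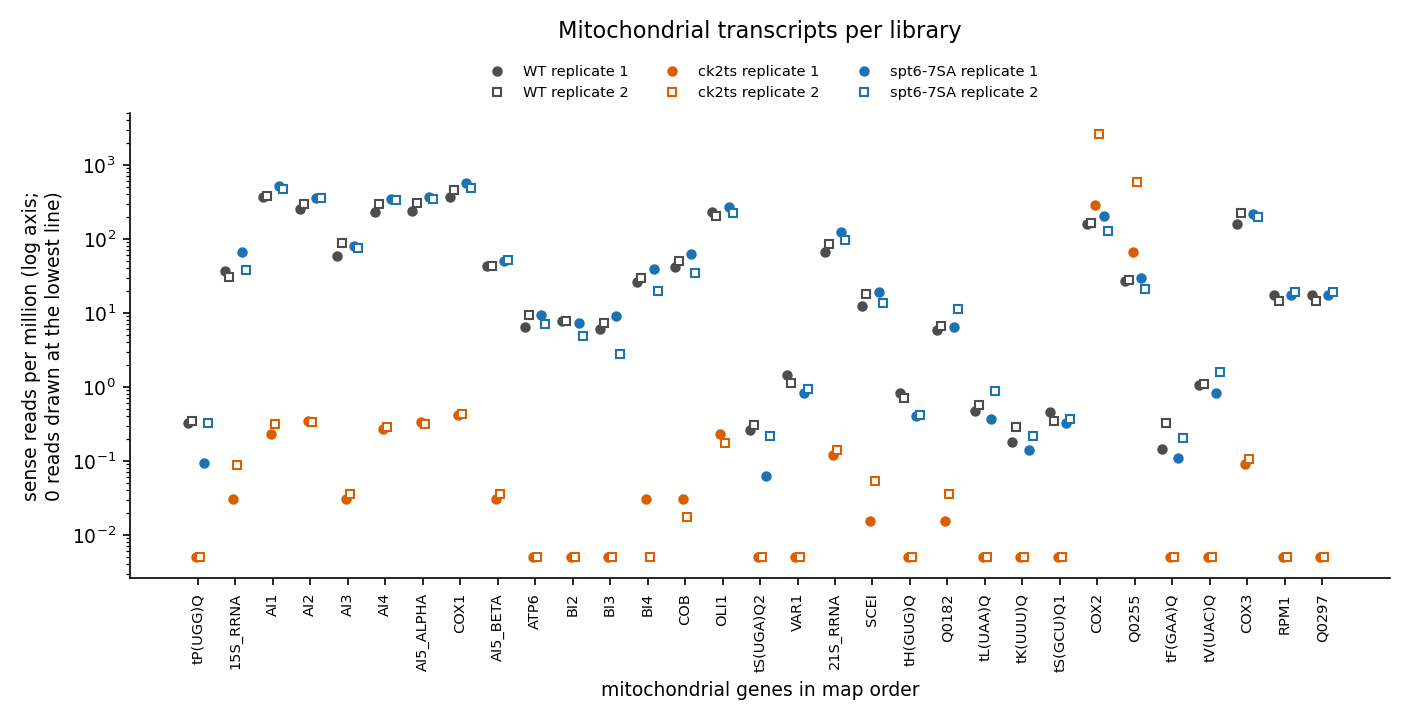
Sense CPM (without TMM, log axis) of the 31 mitochondrial genes with at least 20 reads in WT, in map order; filled circles are replicate 1 and open squares replicate 2 of each group, and 0 reads are drawn at the lowest line. In ck2ts 29 genes lay together at 0.0965% of WT, while COX2 and Q0255 stood at or above WT.

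**Figure D3:**
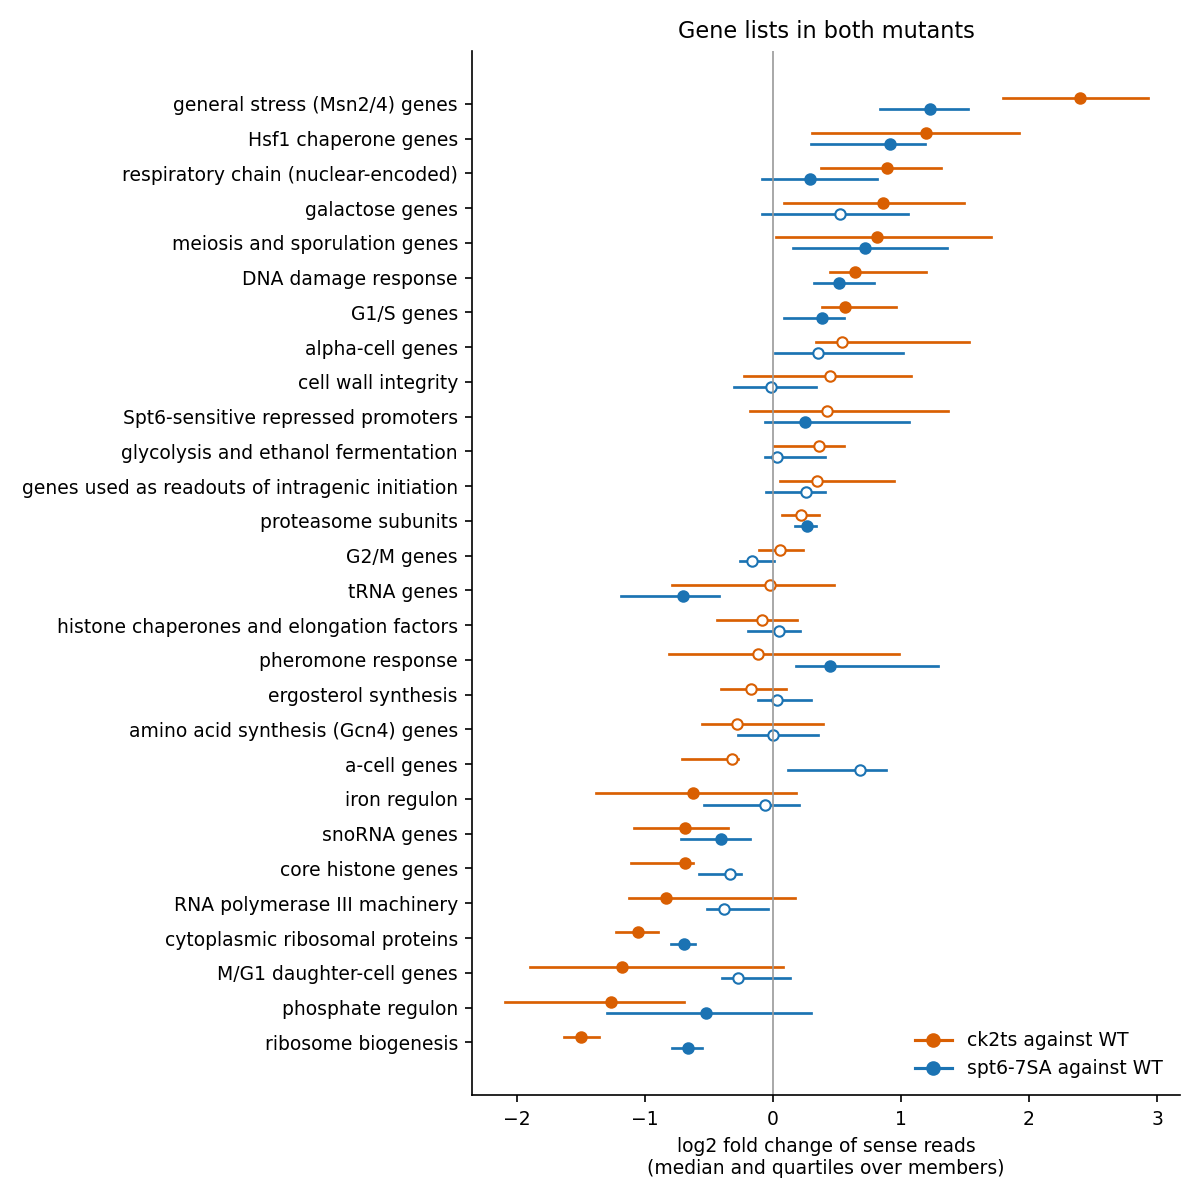
Log2 fold change of sense reads against WT (horizontal axis) for the 28 gene lists other than the mitochondrially encoded one; points are medians over list members, lines span their quartiles, and filled points passed camera at the preset correlation of 0.01. General stress genes had medians of 2.40 in ck2ts and 1.23 in spt6-7SA, and ribosome biogenesis genes -1.50 and -0.66.

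In spt6-7SA against WT, the largest rise among genes chosen in the same way was at SER3 (YER081W, chromosome V, 322686 to 324095), the gene for the first enzyme of serine synthesis, which is repressed by transcription of the noncoding RNA SRG1 across its promoter. SER3 went from 91.9 ± 2.16 to 1205 ± 31.6 CPM (13.1-fold, log2 fold change 3.71, SE 0.16, adjusted p = 5.59e-05). SRG1 itself (chromosome V, 322212 to 322762), read here after the SER3 value was seen, rose from 43.9 ± 6.11 to 59.6 ± 6.74 CPM (adjusted p = 0.0255); its annotated end overlaps the start of SER3 on the same strand, so reads there count for both. Further rises were in LSO1 (7.33-fold), the inducible Hsp70 genes SSA3 (6.75-fold) and SSA4 (4.87-fold), SDH9 (5.73-fold), the lysine synthesis gene LYS1 (5.59-fold), DPI8 (5.06-fold) and the 6-phosphogluconate dehydrogenase gene GND2 (4.94-fold). The largest fall was at PHO89 (YBR296C, chromosome II, 796798 to 798522), from 196 ± 50.7 to 5.96 ± 0.991 CPM (log2 fold change -5.04, SE 0.29, adjusted p = 0.000137). KEI1, for sphingolipid synthesis, fell by 2.94, HXT2 by 2.82, the RNase P subunit gene POP8 by 2.77, the GTPase gene GTR2 by 2.67, YHI9 by 2.46, the RNA export gene YRA2 by 2.44 and SPL2 by 2.23. Of 6778 genes 3442 changed, 1809 up and 1633 down, of which 529 and 220 changed at least 2-fold. The number fell to 2248 without spt6-7SA replicate 1 and to 2294 without replicate 2, and with any 1 library of the 2 groups left out 1185 to 1421 rose and 1055 to 1374 fell.

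Stress and ribosome genes moved in spt6-7SA as follows. Of 35 general stress genes 31 rose and 0 fell (32 when adjusted over the list alone), SPI1 3.87-fold, GAD1 4.34-fold, YGP1 4.36-fold and CTT1 3.65-fold (camera adjusted p = 1.90e-16; adjusted p = 0.536 with an estimated correlation). Of 27 Hsf1 chaperone genes 18 rose and 0 fell (19 when adjusted over the list alone), the Hsp90 gene HSP82 going from 1290 ± 297 to 4294 ± 166 CPM and CPR6, an Hsp90 cochaperone gene, rising 3.10-fold (camera adjusted p = 7.85e-07; adjusted p = 0.536 with an estimated correlation). All 50 ribosome biogenesis genes fell (50 when adjusted over the list alone), with a median log2 fold change of -0.66, DBP2 falling by 1.65 and NOP4 by 1.19 (camera adjusted p = 4.00e-16; adjusted p = 0.536 with an estimated correlation). Of 138 cytoplasmic ribosomal protein genes 132 fell and 0 rose (134 when adjusted over the list alone), RPL27B falling by 1.25 and RPL37B by 0.88 (camera adjusted p = 2.24e-20; adjusted p = 0.536 with an estimated correlation). Of 81 snoRNA genes 24 fell and 0 rose (22 when adjusted over the list alone), with SNR79 falling by 1.03, SNR59 by 0.75 and SNR24 by 0.74 (camera adjusted p = 0.00146; adjusted p = 0.536 with an estimated correlation). Of 144 tRNA genes 16 fell and 0 rose (2 when adjusted over the list alone), tG(GCC)D2 falling by 2.62 and tN(GUU)P by 1.64, though tRNA gene copies can share reads. The tRNA list passed camera (adjusted p = 0.00346, or 0.718 with an estimated correlation) but not fry (adjusted p = 0.151). DNA damage response genes gave 14 rises and 1 fall of 19 (15 when adjusted over the list alone), MAG1 rising 1.88-fold and RNR3 2.20-fold (camera adjusted p = 0.00146; adjusted p = 0.536 with an estimated correlation). DDI2 and DDI3, which are near-identical and can share reads, rose 4.63-fold and 4.75-fold.

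The phosphate regulon gave 10 falls and 4 rises of 16 in spt6-7SA (14 when adjusted over the list alone; camera adjusted p = 0.00148; adjusted p = 0.536 with an estimated correlation), PHO84 going from 3062 ± 109 to 841 ± 53.9 CPM and VTC3 falling by 1.18, while the pair PHO11 and PHO12 rose by 0.43 and 0.44 on the log2 scale. Spt6-sensitive repressed promoters gave 2 rises and 0 falls of 7 (2 when adjusted over the list alone; camera adjusted p = 0.0189; adjusted p = 0.536 with an estimated correlation), SER3 and CYC1, the latter 3.16-fold. PHO5 and SUC2 in that list, at log2 fold changes of -0.04 and -0.13, did not pass. Pheromone response genes gave 11 rises and 0 falls of 17 (11 when adjusted over the list alone), with FIG1 up 3.37-fold, PRM1 3.23-fold and the kinesin gene KAR3 1.45-fold (camera adjusted p = 0.00832; adjusted p = 0.642 with an estimated correlation). Meiosis and sporulation genes gave 13 rises and 2 falls of 24 (16 when adjusted over the list alone), MEK1 rising 2.96-fold and the meiotic recombinase gene DMC1 and SGA1 2.57-fold each (camera adjusted p = 0.00346; adjusted p = 0.585 with an estimated correlation). Respiratory chain genes gave 16 rises and 2 falls of 34 (18 when adjusted over the list alone), SDH1 rising 3.48-fold and NDI1 2.13-fold (camera adjusted p = 0.00453; adjusted p = 0.545 with an estimated correlation). Proteasome genes gave 18 rises and 0 falls of 34 (21 when adjusted over the list alone), PRE6 rising 1.38-fold and PRE10 1.33-fold (camera adjusted p = 0.0195; adjusted p = 0.634 with an estimated correlation). That call ended without spt6-7SA replicate 2 (adjusted p = 0.0523). G1/S genes gave 8 rises and 0 falls of 20 (8 when adjusted over the list alone), SWI4 rising 1.86-fold and RFA1 1.84-fold and CDC45 1.49-fold. The G1/S list passed camera (adjusted p = 0.0348, or 0.735 with an estimated correlation) but not fry (adjusted p = 0.0809). The G1/S call ended without WT replicate 1 (adjusted p = 0.0803) or without spt6-7SA replicate 1 (0.106). In all 14 of 29 lists passed camera at the preset correlation in spt6-7SA; with an estimated correlation 0 passed, 0 at an unadjusted p under 0.05, and 18 passed fry.

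The other lists did not pass camera in spt6-7SA. Core histone genes gave 3 falls and 0 rises of 8 (2 when adjusted over the list alone; camera adjusted p = 0.0892), HTA1 falling by 0.82, HHT1 by 0.61 and HHF1 by 0.27. The inserted construct gives WT and ck2ts, but not spt6-7SA, an added copy of HHT1 and HHF1. Without WT replicate 1 the list passed (adjusted p = 0.0182). Histone chaperone and elongation factor genes gave 6 rises and 7 falls of 36 (12 when adjusted over the list alone; camera adjusted p = 0.830), with a median of 0.05, a mean of 0.01 and a downward test direction; MSI1 fell by 1.07 and VPS75 by 0.67, and SPT21 rose 1.64-fold. Readouts of intragenic initiation gave 7 rises and 2 falls of 14 (9 when adjusted over the list alone; 0.342), APM2 rising 1.73-fold, LCB5 1.52-fold and PUS4 falling by 0.61. RNA polymerase III genes gave 3 rises and 11 falls of 21 (15 when adjusted over the list alone; 0.0865), with MAF1, a repressor of that polymerase, falling by 0.84, and RPC40 by 0.56. A-cell genes gave 3 rises of 6 (3 when adjusted over the list alone; 0.108), STE2 rising 1.93-fold and MFA1 1.82-fold, and the list passed without WT replicate 1 (adjusted p = 0.0280). Alpha-cell genes gave 4 rises of 8 (4 when adjusted over the list alone; 0.127), STE3 rising 1.91-fold and MF(ALPHA)1 3.99-fold. G2/M genes gave 1 rise and 3 falls of 17 (3 when adjusted over the list alone; 0.301), with the cyclin genes CLB1 and CLB2 falling by 1.32 and 1.01, and passed without WT replicate 2 (adjusted p = 0.00462). M/G1 genes gave 3 rises and 3 falls of 14 (3 when adjusted over the list alone; 0.704), the cyclin gene CLN3 falling by 0.69 and DSE4 rising 1.44-fold. Galactose genes gave 4 rises and 2 falls of 8 (6 when adjusted over the list alone; 0.362), GAL7 rising 2.87-fold, GCY1 1.71-fold and GAL80 falling by 0.69. Amino acid synthesis genes gave 9 rises and 9 falls of 38 (18 when adjusted over the list alone; 0.716), MET6 rising 2.74-fold and GCV3 falling by 1.46. Iron genes gave 3 rises and 3 falls of 20 (6 when adjusted over the list alone; 0.735), FRE2 rising 2.03-fold and FTR1 falling by 0.65. Cell wall integrity genes gave 5 rises and 3 falls of 21 (7 when adjusted over the list alone; 0.926), with a median of -0.01, a mean of 0.05 and an upward test direction; PIR3 rose 2.57-fold and DFG5 fell by 0.93. Glycolysis genes gave 4 rises and 0 falls of 16 (0 when adjusted over the list alone; 0.735), PFK2 and HXK2 rising 1.40-fold each. Ergosterol genes gave 3 rises and 3 falls of 20 (4 when adjusted over the list alone; 0.926), ERG9 rising 1.55-fold and ERG13 falling by 0.93.

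The mutants were also compared directly. Relative to ck2ts, spt6-7SA had 8.01-fold more CWP1 (202 ± 2.57 against 25.2 ± 1.74 CPM, adjusted p = 2.15e-06), 9.33-fold more YPR078C, 6.20-fold more IMD2, for guanine nucleotide synthesis, 5.86-fold more of the daughter-cell gene DSE1 and 5.55-fold more of the biotin synthase gene BIO2. It had less FMP16 (log2 fold change -3.58), less of the peroxiredoxin gene TSA2 (-3.42; 21.3 ± 1.64 against 228 ± 10.4 CPM, adjusted p = 2.15e-06), less DDR2 (-3.28), less of the peroxisomal import gene PEX18 (-3.25) and less PRY1 (-3.03). In all 3553 of 6778 genes differed, 1880 higher and 1673 lower in spt6-7SA.

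Changes were then compared between the mutants, because each was set against the same WT libraries. Genes that rose in both numbered 1320, where independent lists of these sizes give 588, and genes that fell in both numbered 1190, where independent lists give 527; 205 went in opposite directions, where independent lists give 1114. HXT2, SPL2, PHO89 and the phosphate genes PHO84 and VTC3 fell in both, and SDH9, SSA4, SER3 and CTT1 rose in both. Simulated unchanged groups set against a shared simulated WT group had at most 2 rises and 1 fall in common in 20 draws. At most 6 genes were called in any simulated comparison, so that small overlap does not measure what the shared WT libraries add. Across genes, which are not independent replicates, the log2 fold changes of both mutants had a Pearson r of 0.551 and a covariance of 0.494, against a simulated mean r of 0.483 (0.420 to 0.536) and covariance of 0.0313, a difference in covariance of 0.463. Unchanged groups compared with a shared WT group correlate by construction, so the r values do not measure what the sharing adds. Part of the excess over independent lists may come from the shared WT libraries. That part was not separated by a split, which would leave 1 WT library to each comparison.

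Antisense reads took a larger share in both mutants. Over genes without an annotated gene on the other strand, antisense reads were 1.45 ± 0.0687% of reads in WT, 2.02 ± 0.156% in ck2ts and 1.78 ± 0.0532% in spt6-7SA. The differences from WT were 0.574 and 0.331 percentage points, with both libraries of each mutant above both WT libraries. The exact two-sided permutation test gave p = 0.33 for each, the smallest value that 2 libraries against 2 allow, and the 95% Wilson intervals of single libraries, which cover counting error only, reached at most 0.0037 points to either side, while the WT libraries lay at 1.40% and 1.49%. Over protein-coding genes with no gene on the other strand within 500 bp, chosen after the data were seen, the differences were 0.894 and 0.638 points (exact permutation p = 0.33 for each). Over all genes, overlapping ones included, the difference of spt6-7SA was 0.15 points (exact permutation p = 0.667). The median share over genes was 1.57 ± 0.0951% in WT, 3.27 ± 0.409% in ck2ts and 2.14 ± 0.0399% in spt6-7SA.

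**Figure D4:**
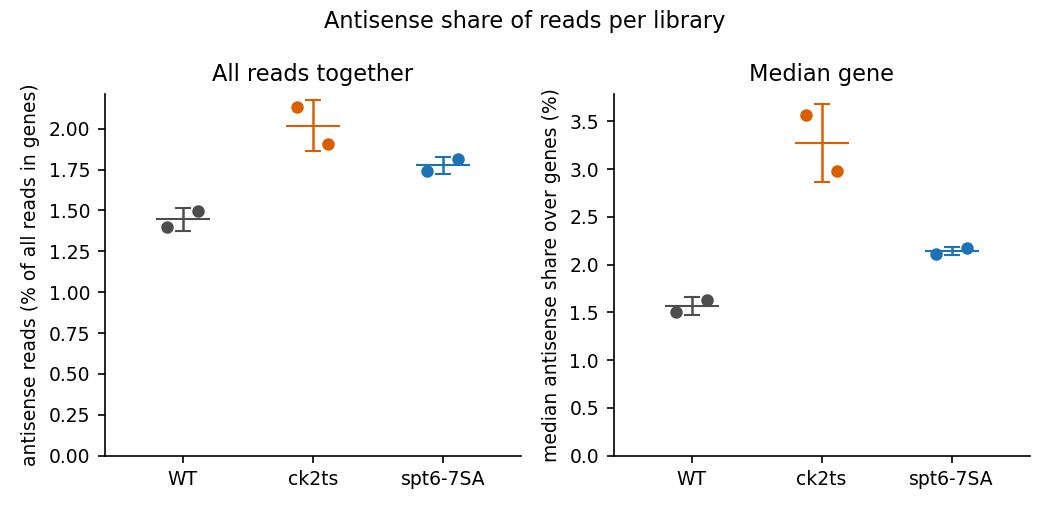
Antisense reads as a percentage of reads in genes without an annotated gene on the other strand (left: all reads together; right: median over genes), by group; points are libraries, and horizontal lines and error bars are the mean and SD of 2 libraries. The shares of all reads were 1.45% in WT, 2.02% in ck2ts and 1.78% in spt6-7SA.

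Among genes with at least 10 antisense CPM in a group, the largest antisense rise in ck2ts was at CKA2 (YOR061W, chromosome XV, 441534 to 442553), the gene altered in this strain, from 0.496 ± 0.0310 to 28.5 ± 3.32 antisense CPM, scaled to sense reads (57.6-fold, adjusted p = 1.35e-11). SSF2 (YDR312W, chromosome IV, 1087581 to 1088942), for ribosome assembly, followed with a 39.7-fold rise, from 0.369 ± 0.0640 to 14.5 ± 0.298, then the ubiquitin ligase gene HEL2 (30.9-fold), the ribosome assembly gene UTP5 (26.8-fold) and the nuclear pore gene NSP1 (19.7-fold). Sense reads of SSF2, HEL2 and UTP5 fell by 1.19, 0.81 and 1.26 on the log2 scale, while those of NSP1 did not pass (log2 fold change -0.18). Antisense reads of LEU2 numbered 2262 in WT and 1 in ck2ts, where its sense reads were missing too, and antisense reads of UPS3 and of the snoRNP gene NOP58 fell by 2.33 and 2.25. Of 5496 genes tested, antisense reads changed at 3414, rising at 2759 and falling at 655, with a median log2 fold change of 0.72. These figures scale antisense reads to the sense reads. Scaled to the antisense reads themselves the median was 0.08, and 3368 genes changed, 1835 up and 1533 down. Among 2137 genes with no gene on the other strand within 500 bp, 1057 rose and 246 fell.

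Among genes with at least 10 antisense CPM in a group, the largest antisense rises in spt6-7SA were at RRI1 (YDL216C, chromosome IV, 68997 to 70319), a COP9 signalosome subunit gene, from 1.92 ± 0.227 to 17.7 ± 0.482 antisense CPM, scaled to sense reads (9.16-fold, adjusted p = 5.28e-09), and at PRO2 (YOR323C, chromosome XV, 921535 to 922905), for proline synthesis, from 1.64 ± 0.0970 to 14.9 ± 0.965 (9.04-fold). GPI8, for GPI anchors, rose 6.20-fold, the splicing factor gene CUS2 5.10-fold and the glycerophosphodiesterase gene GDE1 4.97-fold. Sense reads fell at all 5 of these genes, by 1.54, 1.79, 1.31, 1.97 and 1.09 on the log2 scale. The largest antisense falls among genes at that level were at NNK1 (-1.77), YLR278C (-1.66) and YHR112C (-1.60), where sense reads rose by 0.80, 0.59 and 0.47. Antisense reads changed at 2277 of 5496 genes, rising at 1753 and falling at 524, with a median log2 fold change of 0.33. Without spt6-7SA replicate 2 the number was 1474, and with any 1 library of the 2 groups left out 1164 to 1621 rose and 251 to 398 fell. Among 2137 genes with no gene on the other strand within 500 bp, 883 rose and 129 fell. Scaled to the antisense reads themselves, the median was -0.0048 and 2388 genes changed, 1260 up and 1128 down.

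Antisense reads were tested against the sense reads of the same gene. In ck2ts 3347 of 5496 genes passed, 2561 with antisense reads up relative to sense and 786 down, or 1782 and 1448 when scaled to the antisense reads themselves. By fitted ratio the 3 genes furthest up were the mitochondrial rRNA gene 21S_RRNA, where 10541 sense reads in WT became 16 while antisense reads were 106 and 92, YBR072C-A, with 0 antisense reads in WT and 54 in ck2ts (at least 20.9-fold higher against 3 reads over the group), and CKA2 (log2 ratio change 6.65). Furthest down were YML054C-A, with 0 sense reads in WT and 15 in ck2ts (at least 5.82-fold higher), the peroxisomal oxidase gene POX1 (-5.94), where sense reads rose by 3.08 on the log2 scale, and YNL067W-A (-4.83), with 5 sense reads in WT and 22 in ck2ts. The bounds of the genes at 0 reads do not fix their order among these. In spt6-7SA 2215 genes passed, 1555 up and 660 down, or 1178 and 1165 when scaled to the antisense reads themselves. With any 1 library of the 2 groups left out 1038 to 1476 went up and 390 to 497 down. The genes furthest up were the nuclear pore gene NUP145 (6.27; 20 antisense reads in WT and 867 in spt6-7SA), SRG1, with 0 antisense reads in WT and 25 in spt6-7SA (at least 8.55-fold higher, which does not fix its order), and YFL032W (5.86). Furthest down were YAR035C-A (-4.71), with 1 sense read in WT and 34 in spt6-7SA, HIS3 (-4.39), deleted in part in this strain, and the stress gene YGP1 (-4.16), where sense reads rose 4.36-fold. The YAR035C-A call ended without WT replicate 1 (log2 ratio change -3.18).

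Between the mutants, antisense reads differed at 2647 of 5496 genes, 756 higher and 1891 lower in spt6-7SA than in ck2ts, or 1341 and 1463 when scaled to the antisense reads themselves, and at 1760 without spt6-7SA replicate 1. With any 1 library of the 2 groups left out 456 to 810 were higher and 1257 to 2027 lower. Among genes with no gene on the other strand within 500 bp, 407 were higher and 584 lower. Antisense reads rose in both mutants at 1363 genes, where independent lists give 880, and fell in both at 235, where independent lists give 62.4. These numbers were 898 and 186 without WT replicate 1, and 1262 and 146 without WT replicate 2. At 133 genes they went in opposite directions, where independent lists give 472. Simulated unchanged groups shared at most 1 gene in each direction, but at most 4 genes were called in any simulated comparison. That small overlap therefore does not measure what the shared WT libraries add. Across genes, Pearson's r was 0.575 and the covariance 0.823, against simulated means of 0.487 and 0.0858, a difference in covariance of 0.737. The r values have the same limit as for sense reads, and part of the excess may again come from the shared WT libraries.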

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

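The counts in 5' and 3' parts of genes were outside the main comparisons, and the comparison of these parts, the test on genes away from neighbours and the test on sense coverage were chosen only after the result was seen.

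Over 3143 genes of at least 1000 bp, the 5' part held 12.5 ± 0.348% of antisense reads in WT, 13.9 ± 0.419% in ck2ts and 16.6 ± 0.0305% in spt6-7SA (n = 2). The 3' part held 18.4%, 14.3% and 14.7%. Run-in from neighbouring genes would be less where no annotated gene lies on the other strand within 500 bp, though transcription from further away could still reach these genes. There the difference from WT fell from 4.16 to 2.56 points in spt6-7SA (15.5% against 13.0%). In ck2ts it fell from 1.46 to 0.371 points (13.3%). Since the filter does not remove all run-in, run-in stays open as a source in both mutants. In spt6-7SA the difference from WT was 6.22 points without the 100 genes richest in antisense reads, more than with all genes. A few such genes were therefore not the source there. A shift of coverage to the 3' ends of RNAs would raise the 3' to 5' ratio of sense reads as much. In spt6-7SA the sense ratio rose by a factor of 1.12 and the 5' to 3' ratio of antisense reads by 1.67. Such a shift was therefore not the whole cause there. Neither explanation was tested in ck2ts, where the difference without those 100 genes was 2.24 points. Its sense factor was 1.06 and its antisense factor 1.44, or 1.06 and 1.17 away from neighbours. The differences between the strains stay open and were not tested.

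Sense reads differed between the 3' and the 5' part in ck2ts at 88 of 2970 genes, 68 towards the 3' part and 20 towards the 5' part, and in spt6-7SA at 27, 26 towards the 3' part and 1 towards the 5' part. In ck2ts the catalase gene CTA1 (log2 ratio change 4.33) moved to the 3' part and SDH9 (-6.75) to the 5' part. CKA1 had a log2 ratio change of 6.83, but ck2ts lacks this gene. Only 202 and 100 of its reads were left there, with 2 and 1 in the 5' part. In spt6-7SA the kinetochore gene DAM1 (3.97), ARO80 (2.88) and CTA1 (2.82) moved to the 3' part. These genes were chosen after their values were seen. With each part scaled by its own TMM, which sets the overall level by construction, 53 genes went towards the 3' part and 34 towards the 5' part in ck2ts, and 23 and 2 in spt6-7SA. The median log2 ratio change over genes went from 0.12 to -0.04 in ck2ts and from 0.16 to -0.0059 in spt6-7SA. Without that scaling and with 1 library left out, it ran from 0.055 to 0.187 in ck2ts and from 0.102 to 0.203 in spt6-7SA. The numbers rested on single libraries. In ck2ts they were 4 without WT replicate 1, 10 without WT replicate 2, 30 without ck2ts replicate 1 and 63 without ck2ts replicate 2. In spt6-7SA they were 5 and 8 without WT replicates 1 and 2, and 8 and 4 without spt6-7SA replicates 1 and 2. A library left alone in its group was assumed to vary like the other groups.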

How the results depend on the processing

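The 500 bp variant of the antisense share and the settings of the 3' and 5' parts were chosen only after the data were seen; the other alternatives were planned. Of 654 values of 70 named gene results under the alternatives, 653 kept their direction and their side of the threshold. YAR035C-A, antisense against sense, lost its call without WT replicate 1 (log2 ratio change -3.18). The named genes were chosen as the largest passing changes in the same data, so their stability does not speak for other calls. Of 406 values for lists 349 kept their call, 37 lost and 20 gained one. Of 110 counts and shares 93 stayed close, within 1.5-fold for total counts and within the larger group SD for shares. Named genes, lists and shares had 0 reversals, but counts were not checked for direction. A close total can hide a changed balance. Scaled to the antisense reads themselves, antisense changes in ck2ts went from 2759 up and 655 down to 1835 and 1533. Leaving out each library gave 3750 to 4113 sense genes in ck2ts, 2248 to 2795 in spt6-7SA (2248 without its replicate 1, 2294 without its replicate 2) and 2495 to 3218 between the mutants. For antisense genes the ranges were 2862 to 3395, 1474 to 1961 (1474 without spt6-7SA replicate 2) and 1760 to 2644 (1760 without spt6-7SA replicate 1), and for antisense against sense 2825 to 3373 and 1515 to 1973. The antisense share differed from WT by 0.464 to 0.684 points in ck2ts and 0.283 to 0.380 in spt6-7SA, shared sense changes by direction numbered 1703 to 2072 and shared antisense changes 1084 to 1408, and 16 to 17 and 13 to 15 lists passed. With only the genes that have no gene on the other strand within 500 bp, 2137 genes were tested for antisense reads rather than 5496. Of these 1303, 1012 and 991 differed (ck2ts, spt6-7SA and between the mutants). Fewer genes were not the only change. The median log2 fold change went from 0.72 to 0.70 in ck2ts, from 0.33 to 0.56 in spt6-7SA and from -0.32 to -0.09 between the mutants. The antisense share differed there by 0.894 and 0.638 points. With all genes it differed by 0.389 and 0.15 points, since overlapping genes add reads of their neighbours, and the median over genes by 1.71 and 0.577 points; the cause was not tested. With at least 2-fold changes, 437 sense and 1036 antisense changes were shared, a stricter threshold by construction. With an estimated correlation camera passed 0 lists in ck2ts (2 at an unadjusted p under 0.05) and 0 in spt6-7SA (0 unadjusted), where fry passed 23 and 18. Scaling antisense reads to themselves moved the median of all genes from 0.72 to 0.08 in ck2ts and from 0.33 to -0.0048 in spt6-7SA. DESeq2 called 4439, 3577 and 3670 sense and 2988, 1858 and 2166 antisense genes. The labels tie replicates by number only, though replicate 2 had the higher SCR1 share in every group; deviations of replicate 1 correlated across genes by 0.351, 0.294 and 0.395 for sense and 0.0087, 0.136 and 0.0581 for antisense reads, and a replicate block gave 5005, 4387 and 4428 sense and 3422, 2254 and 2646 antisense genes, ended the galactose call in ck2ts (adjusted p = 0.0579) and added the alpha-cell list in ck2ts (0.0492) and core histones in spt6-7SA (0.0397). Of simulated 2-fold changes 82% were called for sense reads, 48% for antisense reads and 24% for antisense against sense; depth and spread were not separated as causes.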

Other observations

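All tests of explanations in this part were chosen only after the result was seen.

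Antisense reads were a larger share in both mutants than in WT. Weaker strand separation would give wrong-strand reads in step with sense reads, but over the 100 protein-coding genes with most sense reads the median antisense share was at most 0.0703% in a mutant library, below the rise of 0.331 points in spt6-7SA. Reads of genomic DNA would add as many reads per kb everywhere. The 1357 of 5425 genes with fewest antisense reads per kb were chosen over all 6 libraries, mutants included. They gained 0.286 of the gain per kb of all genes in ck2ts and 0.21 in spt6-7SA. Choosing genes partly by low mutant values itself lowers their gain, so this ratio does not settle whether DNA was a source. Whether antisense RNA rose per cell or sense RNA fell cannot be told apart without a spike-in; scaled to themselves, antisense reads rose at 1835 genes in ck2ts. The strain differences themselves stay open and were not tested.

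Nearly all mitochondrial transcripts were absent in ck2ts. Lower recovery of mitochondrial RNA would lower COX2 and Q0255 too, but the lowest ratio of either to WT in a ck2ts library was 1.79. A loss of most of the mitochondrial genome with the stretch at COX2 kept may explain the pattern, since the other genes stood together at 0.0965% of WT and the 2 kept genes formed 1 stretch. Both ck2ts libraries lacked these transcripts and nearly all LEU2 reads, and differed from WT in the 5' share of LYS2 reads. This concerns the 2510 sense changes that spt6-7SA shared in direction and the other 1879 of ck2ts. For both sets, these differences and loss of kinase activity cannot be told apart.

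Sense reads fell at the 5 genes with the largest antisense rises in spt6-7SA among those with at least 10 antisense CPM, which raised the hypothesis that antisense rises go with sense falls. NUP145 and YFL032W had larger antisense rises from a lower level and, with SRG1, were the genes furthest up in antisense against sense. Sense reads fell at NUP145 (log2 fold change -0.82), rose at SRG1 (0.44) and did not pass at YFL032W (-1.30). Ranking by that ratio favours sense falls by construction, so these genes do not bear on the hypothesis. Across 2002 protein-coding genes with no gene on the other strand within 500 bp, Spearman's rho was -0.0667, and sense reads fell at 33.6% and rose at 26.6% of the 587 genes where antisense reads rose at least 2-fold, against 26.2% and 28.3% of the 1037 where they did not pass. Over 5199 protein-coding genes without overlap these shares were 30.6% and 27.8% against 25.4% and 25.4%; in ck2ts sense reads fell at 36.5% against 35.1% of the first set and 33.3% against 36.6% of the second. Genes are not independent replicates, and the hypothesis stays open.

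Most retrograde response genes, in a list added after the data were seen, rose in both mutants. In ck2ts 8 of 11 rose and 2 fell (11 when adjusted over the list alone; camera p = 0.00804, not adjusted for the other lists; p = 0.362 with an estimated correlation), among them MLS1, PYC1, CIT2 and ACO1. In spt6-7SA, which kept its mitochondrial transcripts, 9 rose and 1 fell (10 when adjusted over the list alone; camera p = 5.15e-05, not adjusted either; p = 0.204 with an estimated correlation), among them CIT1, CIT2, PDH1 and IDH2.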
